A study of Mus musculus with 6 samples.

How the data were processed

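RNA was extracted with Trizol from whole prostates frozen on dry ice, and polyadenylated RNA was made into strand-preserving libraries with NEBNext kits, per the labels' protocols. Sequencing was single-end on an Illumina NextSeq 500. The submitters' processing notes name STAR, DESeq2 and the mm10 genome build, with no versions and no roles. The program that counted reads per gene, its annotation and its strand setting are not given in the sources used here, so overlapping genes and antisense partners could not be told apart with certainty. The authors deposited 1 table of whole-number read counts for 24421 gene symbols in 6 libraries, with no normalization. The columns matched the sample labels by title, and 0 columns were left unmapped. Groups came from the genotype label, and replicate numbers follow the order of the samples and pair nothing.

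Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter with a minimum count of 10, which left 13762 genes, and libraries were scaled by TMM factors. The comparison of 3 knockout and 3 control libraries used the quasi-likelihood F test with no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. CPM values are scaled by the TMM factors. The median log2 fold change over all tested genes was 0.03. With library size alone as the scaling it was -0.10, and with upper-quartile factors 0.08. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The common biological coefficient of variation was 32.5%.

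Gene lists, 35 in all, were fixed before the data were examined, and 32 had at least 5 tested members. The lists left out were seminal vesicle genes, red blood cell genes (1 tested) and mitochondrially encoded genes (0 in the table). Lists were tested with limma 3.58.1 by camera with a preset inter-gene correlation of 0.01, by camera with an estimated correlation and by fry, each adjusted over the 32 lists. The estimated setting also uses the few residual degrees of freedom of the fit, so it is stricter than the preset even at an equal correlation. The naming rule, also fixed before the data were examined, took Sqstm1, Atf4 and S100a4, and the 12 largest rises and 12 largest falls among genes past the threshold. Those had a mean log2 CPM of at least 1, no overlap between groups and no predicted, clone, pseudogene or receptor-segment name. It also took up to 4 members with the smallest p in the direction of each list, and Asns, Psat1, Phgdh, Pcx and Slc7a11. Genes outside the rule are marked as named after their values were seen. These also include, with no mark beside them, Ifit2, Nfkb1, Ltbp2, Btg2, Shmt1, Csf1r, Adgre1, Krt8, Krt18 and the genes of the closing section.

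Coordinates came from GENCODE M21 on GRCm38, the assembly of mm10, to which 13279 of the tested symbols (96.5%) were matched. Files were checked for duplicated libraries by a chi-square per gene over each pair, which was 51.0 to 944 and so far above sampling noise. Reads carry no molecular identifiers, so intervals and floors cover counting error only. For a gene with 0 counts in a group the floor was 3 counts over the group.

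The test was checked on simulated counts drawn from the control means and the real library sizes and dispersion, with 3 libraries against 3 and 13381 genes tested. It recovered 5 of 100 genes changed 2-fold and 69 of 99 changed 4-fold (69.7%), with 3 false calls (3.90% of calls). Fewer genes were changed in the simulation than were called in the real data, which makes its adjusted threshold stricter. A planted gene list was found and 0 of 30 unchanged lists were called. Simulated genes were drawn independently, so this does not check list calls where members vary together. The estimated correlation was 0.68 for smooth muscle and 0.78 for unfolded protein response chaperones, against 0.011 for ATF4 targets. Alternatives fixed before the data were examined were size factors, upper-quartile factors, library size alone, TMM factors without the 50 most abundant genes, no count filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, other thresholds, and leaving out each library in turn. Alternatives chosen after seeing the data left out control 3 and knockout 1 together, or added the summed CPM of Sbp, Sbpl and Spink1 relative to control 3 as a covariate (the ventral-type secretory level). Pseudocount alternatives were planned for normalized values and did not apply to counts.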

Results

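Whole prostates of C57BL/6 mice aged 52 weeks were profiled by sequencing of polyadenylated RNA. The control group held 3 libraries from mice with floxed alleles of p62, which the labels call wild type. The stromal p62 knockout group held 3 libraries from floxed mice that also carried a Cre recombinase named for FSP1, the fibroblast-associated protein encoded by S100a4. p62 is the autophagy adaptor and signalling scaffold encoded by Sqstm1. The series title frames the question as how p62 acts on the stress-response transcription factor ATF4 and on stromal metabolism. The comparison made here was therefore knockout against control, over all genes and over lists of ATF4 target, metabolic and cell-type genes. Total counts were 20011908, 16052785 and 12826463 for control 1, 2 and 3, and 14761703, 24186958 and 26910053 for knockout 1, 2 and 3. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples.

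The libraries of a group were not equally alike. Control 1 and 2 had a Spearman correlation across genes of 0.985, and knockout 2 and 3 had 0.986. Control 3 correlated with the other 2 controls at 0.942 and 0.938, and with the knockout libraries at 0.840 to 0.873. Control 1 and 2 correlated with knockout 2 and 3 at 0.943 to 0.948, no lower than with control 3, and with knockout 1 at 0.914 and 0.915. Knockout 1 correlated with knockout 2 and 3 at 0.958 and 0.953. The most abundant gene in control 1, control 2 and all 3 knockout libraries was 9530053A07Rik, with 13.1% to 24.9% of the counts. In control 3 the most abundant gene was Sbp, with 10.2% of the counts, and 9530053A07Rik stood at 129 CPM (TMM-scaled counts in a library of 1e6 counts) against 127810 and 191366 CPM in control 1 and 2. The 10 most abundant genes took 24.1% to 34.3% of each library.

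Sqstm1 RNA was not lower in the libraries labelled knockout. The gene (GRCm38 chromosome 11, 50199366 to 50210827, minus strand) was measured at 355 ± 57.4 CPM (SD, n = 3) in controls and 463 ± 76.8 CPM (SD, n = 3) in knockouts. Its log2 fold change was 0.39 ± 0.23 (SE), with an adjusted p of 0.355 in edgeR's quasi-likelihood test. The deletion is directed to stromal cells and the counts cover the whole gene in the whole organ, so Sqstm1 did not check the labels, and the groups are named here as the labels give them. Atf4 (chromosome 15, 80255184 to 80257541, plus strand) was at 174 ± 58.9 CPM in controls and 433 ± 94.8 CPM in knockouts (SD, n = 3 each). All 3 knockout values lay above all 3 control values, and the log2 fold change was 1.31 ± 0.31 (SE), but the adjusted p of 0.0585 (edgeR) missed the threshold of 0.05. The call for Atf4 depended on the tool and the scaling, with an adjusted p of 7.41e-04 in DESeq2 and 0.0497 in limma-voom. With the level of ventral-type secretory genes as a covariate, which is near 0 in all knockouts, the log2 fold change of Atf4 was 0.56 (adjusted p = 0.808, edgeR). S100a4 (chromosome 3, 90603771 to 90606045, plus strand) was at 6.29 ± 1.96 CPM in controls and 9.62 ± 5.66 CPM in knockouts (adjusted p = 0.455, edgeR).

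Most of the genes that changed were lower in the knockout. Of 13762 genes tested, 698 passed a false discovery rate of 0.05, with 57 higher and 641 lower (91.8% lower). Among the lower genes 239 fell by over 8-fold, while 7 of the higher genes rose by over 8-fold. All 698 had no overlap between the 3 values of each group. Over all tested genes 4462 (32.4%) had no overlap, where chance gives 10%. In total 3045 genes had an unadjusted p under 0.05. The count was 255 without knockout 2, 282 without knockout 3, 446 without control 1 and 453 without knockout 1. DESeq2 called 1582 genes, of which 1162 were lower (73.5%). With the ventral-type secretory level as a covariate 170 genes passed, and without control 3 and knockout 1 there were 1229 (70.1% lower).

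Of the 12 largest falls 4 were on the prostate secretory list: Sbp, Sbpl, Spink1 and Abo. Sbp (spermine binding protein), Spink1 (a trypsin inhibitor of Kazal type) and Sbpl were each above 10000 CPM in all controls and under 50 CPM in all knockouts. Sbp (chromosome 17, 23941672 to 23945607, plus strand) was at 43697 ± 40928 CPM in controls and 17.0 ± 20.7 CPM in knockouts (SD, n = 3 each; log2 fold change -11.34 ± 1.85 SE; adjusted p = 0.0148, edgeR). Spink1 (chromosome 18, 43728082 to 43737557, minus strand) was at 30078 ± 11355 and 12.5 ± 16.7 CPM, with an adjusted p of 0.0094. Sbpl, beside Sbp on chromosome 17, was at 19270 ± 11130 and 8.12 ± 10.1 CPM, with an adjusted p of 0.00832. Sbp and Sbpl are related copies, so the division of reads between them is uncertain. Their calls missed the threshold without knockout 2, at adjusted p = 0.0815 for Sbp, 0.0544 for Spink1 and 0.0543 for Sbpl. Abo, a glycosyltransferase gene of the blood group locus, went from 876 ± 455 to 0.21 ± 0.15 CPM (adjusted p = 4.38e-04). Scgb2b27, of the secretoglobin family, went from 1491 ± 1038 to 0.58 ± 0.87 CPM (adjusted p = 0.00532).

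The other genes among the 12 largest falls had at most 2 counts over the 3 knockout libraries, with 63.5 (in units of 1e6) scaled counts in all. Ratios of pooled control to pooled knockout level are given for these genes with 95% intervals that cover counting error only. The ratio was 11200 (2020 to 444000) for Scgb1b27, 6230 (1720 to 51500) for the calcium channel gene Trpv6 and 5410 (1500 to 44700) for Wfdc3. It was 5560 (997 to 219000) for Crabp1, which encodes a retinoic acid binding protein, and 3930 (705 to 155000) for the monocarboxylate transporter gene Slc5a8. Scgb2b24 and Lrrc52 had 0 counts in all 3 knockouts, and against a floor of 3 counts over the group they were at least 790-fold and at least 372-fold lower. Secretoglobin genes lie in a family of near-identical copies, so their individual values are uncertain.

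In the list of prostate secretory genes 5 of 9 tested members fell and none rose, and adjusted over the list alone 7 fell. The members that fell were Sbp, Spink1, Sbpl, Abo and Msmb, the last named after its values were seen. Msmb was at 1.27 CPM in control 1 and at 311 and 346 CPM in control 2 and 3, against 0.08 to 1.20 CPM in knockouts, and its call was kept in 1 of the 6 fits with a library left out. The set was lower by camera with a preset correlation (adjusted p = 8.81e-08), with an adjusted p = 0.231 with an estimated correlation and an adjusted p = 0.0251 in fry. Secretory genes also differed among the controls. Tgm4, the prostate transglutaminase, was at 32009 and 34344 CPM in control 1 and 2 and at 21.8 CPM in control 3, against 45016 to 49776 CPM in knockouts. Pbsn (probasin) was at 9754 and 8716 CPM in control 1 and 2, 546 CPM in control 3 and 15600 to 37873 CPM in knockouts. Neither passed the test between groups (adjusted p = 0.712 and 0.266, edgeR). Tgm4 and Pbsn were named after their values were seen.

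**Figure D1:**
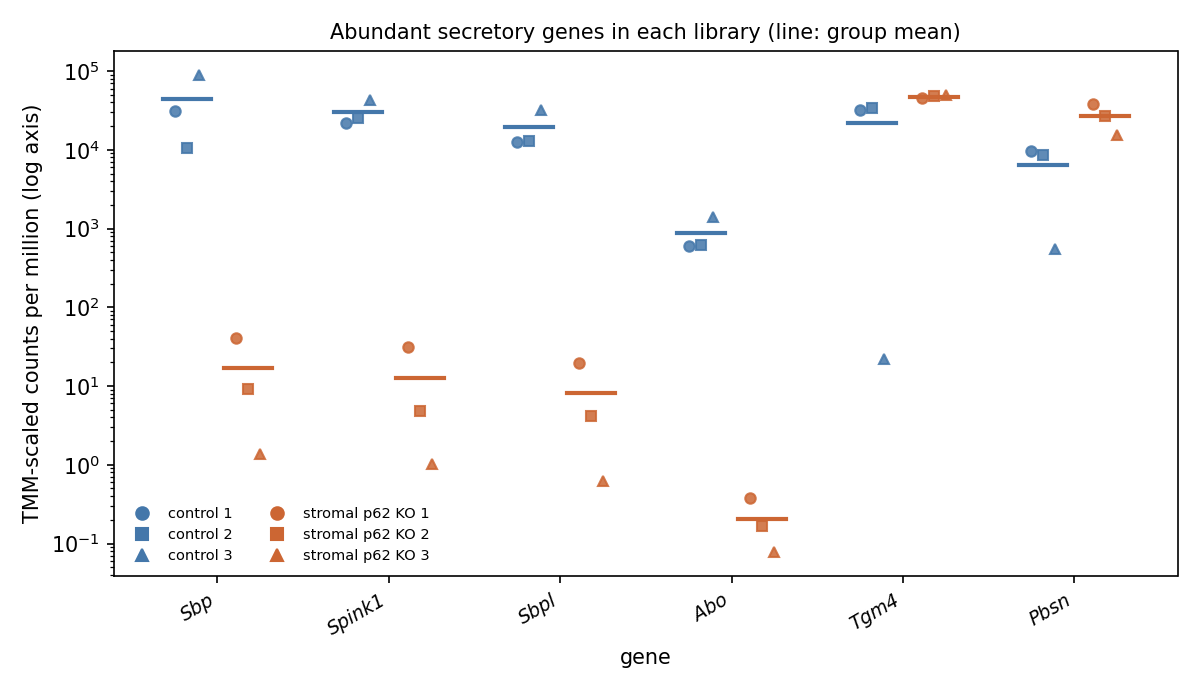
TMM-scaled CPM on a log axis for 6 secretory genes, with 1 point per library and a line at the mean of each group. Sbp, Spink1, Sbpl and Abo were far lower in all 3 knockout libraries, while Tgm4 and Pbsn were lowest in control 3, at 21.8 and 546 CPM.

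The 12 largest rises took in a heat shock gene, interferon-inducible GTPases and a clock gene. Hspa1b, an inducible Hsp70 gene, rose from 12.4 ± 4.18 to 190.1 ± 163 CPM (SD, n = 3 each; log2 fold change 3.94 ± 0.84 SE; adjusted p = 0.0411, edgeR), with knockout values of 352, 25.6 and 192 CPM. It shares most of its sequence with Hspa1a, so its reads are uncertain, and its call was lost when any library other than knockout 2 was left out (adjusted p = 0.101 to 0.128). Adm2, which encodes a peptide of the adrenomedullin family, rose with a log2 fold change of 3.57 ± 0.74. Egflam, a matrix protein gene, rose by 2.61 ± 0.31 on the log2 scale and had the smallest adjusted p of the 12 (0.00443). Iigp1 and Gbp4, which encode interferon-inducible GTPases, rose by 2.55 ± 0.39 and 1.98 ± 0.36. Arntl, which encodes the clock transcription factor BMAL1, rose from 4.44 ± 0.12 to 22.1 ± 8.45 CPM (adjusted p = 0.00712). Ahr, the aryl hydrocarbon receptor gene, rose from 21.3 ± 6.91 to 101 ± 39.4 CPM, and Cpe (carboxypeptidase E) from 24.9 ± 13.3 to 121 ± 64.1 CPM. The others were Tmem71, Crym, Rdh12 and Upb1, with log2 fold changes of 1.83 to 2.38. With a library left out, Egflam, Arntl and Ahr kept their call in all 6 fits, Adm2 in 2, Tmem71 and Rdh12 in 1 and Cpe in 0. With the ventral-type secretory covariate 0 of the 12 rises kept their call. The adjusted p was then 0.122 for Egflam, 0.157 for Arntl, 0.334 for Ahr and 0.897 for Adm2, whose log2 fold change was 1.07. Under all alternatives, this covariate included, the log2 fold change was at least 2.40 for Egflam, 2.28 for Iigp1, 1.97 for Arntl and 1.96 for Tmem71. The lowest values of the other rises ran from 1.07 for Adm2 to 2.32 for Hspa1b.

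Targets of ATF4, the transcription factor of the integrated stress response, were higher as a group in the knockout by camera with the preset correlation (adjusted p = 1.52e-04), with an adjusted p = 0.231 with an estimated correlation. The correlation estimated for this list was 0.011, near the preset 0.01. Of 37 tested members 5 rose, 1 fell and 31 did not pass. Adjusted over the list alone, 19 rose and 4 fell. The serine synthesis enzyme genes Psat1 and Psph rose from 49.1 ± 17.9 to 142 ± 29.4 CPM and from 11.9 ± 1.20 to 32.0 ± 5.80 CPM (SD, n = 3 each; adjusted p = 0.0278 and 0.00981, edgeR). The stress factors Atf5 and Trib3 rose by 1.58 ± 0.28 and 1.82 ± 0.36 on the log2 scale, and the cystine transporter gene Slc7a11 by 1.29 ± 0.27. Asparagine synthetase, Asns, stood at 171 ± 67.4 and 433 ± 82.2 CPM with an adjusted p of 0.0727. Phgdh, the entry enzyme of serine synthesis, stood at 214 ± 5.56 and 225 ± 40.1 CPM (adjusted p = 0.840). Pcx, pyruvate carboxylase, stood at 64.9 ± 28.0 and 38.8 ± 2.88 CPM (adjusted p = 0.192). The member that fell was Nupr1, a stress-induced chromatin factor named after its values were seen, from 1221 ± 253 to 4.08 ± 1.94 CPM (log2 fold change -8.24 ± 0.48; adjusted p = 4.38e-04).

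The median log2 fold change of the ATF4 list was 0.85. Its median log2 level relative to the mean of the 6 libraries was -0.25, -0.23 and -0.57 in control 1, 2 and 3, and 0.41, 0.39 and 0.45 in knockout 1, 2 and 3. The set also passed by fry (adjusted p = 0.0256). By camera it kept its direction and its call without each library in turn (adjusted p of 2.82e-05 to 5.36e-04). Single calls were weaker: Psat1, Atf5, Trib3 and Slc7a11 each missed the threshold when any of at least 4 libraries was left out. Psph missed it without knockout 2, at adjusted p = 0.0521.

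**Figure D2:**
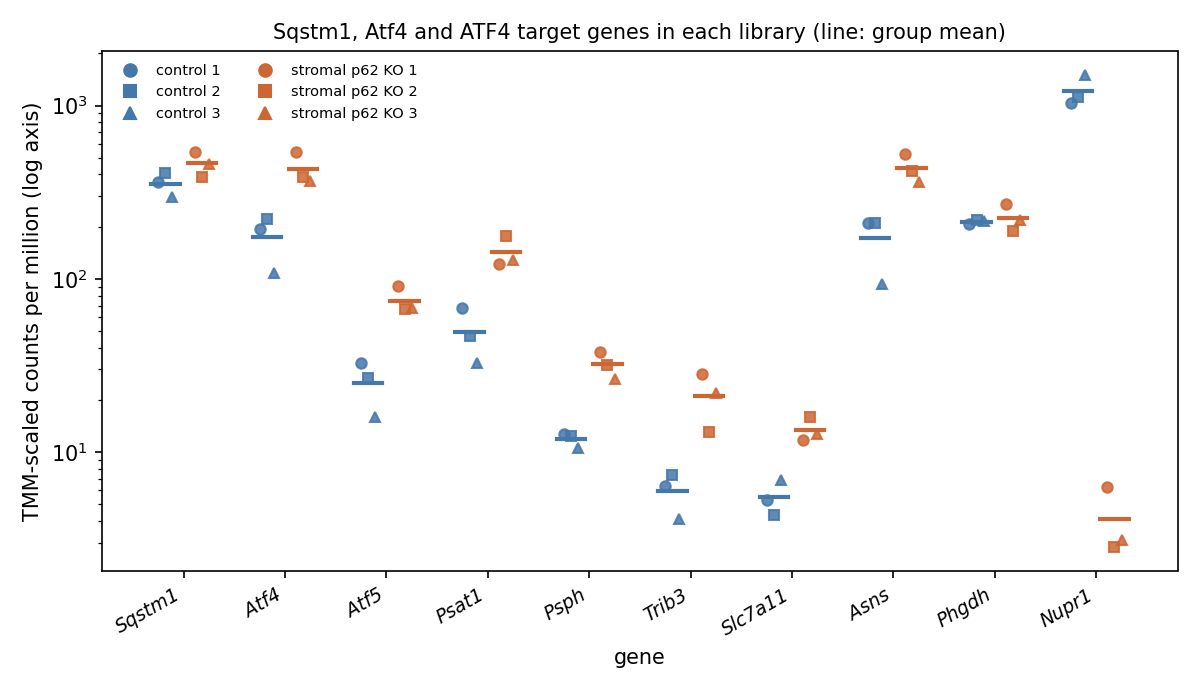
TMM-scaled CPM on a log axis for Sqstm1, Atf4 and 8 ATF4 target genes, with 1 point per library and a line at the mean of each group. The knockout values of Psat1, Psph, Atf5, Trib3 and Slc7a11 all lay above the control values, Nupr1 lay far below, and Sqstm1 overlapped.

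Other lists of amino acid and one-carbon metabolism had few members past the threshold. Of 20 aminoacyl-tRNA synthetase genes, which charge tRNAs for translation, none passed over all genes and 7 rose adjusted over the list alone. Mars, Tars, Cars and Eprs had log2 fold changes of 0.68, 0.65, 0.96 and 0.72. The set was higher by camera (adjusted p = 4.03e-04), with an adjusted p = 0.841 with an estimated correlation. Its median in control 3 was -0.59 against -0.15 and -0.08 in the other 2 controls, and the call was lost with the ventral-type secretory covariate (adjusted p = 0.326). In serine, glycine and one-carbon metabolism 2 of 23 rose (Psat1 and Psph) and 2 fell, and adjusted over the list alone 5 rose and 2 fell. The members that fell, named after their values were seen, were Mat2a, which makes S-adenosylmethionine (3573 to 219 CPM, adjusted p = 0.00443), and the cytosolic enzyme gene Shmt1 (adjusted p = 0.0402), whose call was kept in 1 of the 6 fits with a library left out. The mitochondrial enzymes Mthfd2 and Shmt2 had log2 fold changes of 0.94 and 0.90, with adjusted p of 0.0701 and 0.0726. In glutamine, asparagine and aspartate metabolism 2 of 20 fell, and adjusted over the list alone 2 rose and 2 fell. Asrgl1, an asparaginase gene, fell from 401 to 16.8 CPM, and Cad, of pyrimidine synthesis, from 320.0 to 44.4 CPM (adjusted p = 0.00229 and 0.00559). Neither of these 2 lists passed as a set (adjusted p = 0.703 and 0.190 by camera). Mat2a, Asrgl1 and Cad were highest in control 3, as Sbp, Sbpl and Spink1 were, while Shmt1 was not. Mat2a was at 2671, 2159 and 5890 CPM in control 1, 2 and 3. Asrgl1 was at 269, 299 and 634 CPM and Cad at 239, 268 and 453 CPM in these controls. Whether these falls share a cause with the secretory genes was not tested.

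Central carbon metabolism changed in few members. In glycolysis 1 of 20 fell, both over all genes and adjusted over the list alone: Hk2, a hexokinase, from 143 ± 48.2 to 2.83 ± 1.17 CPM (adjusted p = 7.07e-04). Hk2 was highest in control 3, at 110, 122 and 199 CPM in control 1, 2 and 3. None of 28 TCA cycle genes passed by either adjustment, and Idh1 had a log2 fold change of 1.00 with an adjusted p of 0.0565. In NRF2 targets, of the antioxidant response, 1 of 27 rose (Slc7a11), and adjusted over the list alone 2 rose and 1 fell. In autophagy and lysosome genes 1 of 32 fell by either adjustment, the protease gene Ctsl (adjusted p = 0.0321), whose call was lost in all 6 fits with a library left out. None of these 4 lists passed as a set (adjusted p of 0.435 to 0.834 by camera). The nuclear-encoded oxidative phosphorylation list had no member past the threshold by either adjustment among 40, with 36 positive log2 fold changes and a median of 0.39. The set was higher by camera (adjusted p = 0.00237), with an adjusted p = 0.841 with an estimated correlation. The list median stood at 0.72 in knockout 1 and at -0.04 and -0.09 in knockout 2 and 3, and without knockout 1 the adjusted p was 0.149.

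Among stromal cell types, smooth muscle genes were higher as a set in the knockout by camera (adjusted p = 1.63e-05), with an adjusted p = 0.841 with an estimated correlation. All 18 had positive log2 fold changes, none passed over all genes and 2 rose adjusted over the list alone, Lmod1 and Mylk (log2 fold changes of 0.92 and 1.30). The list median was -0.42, 0.09 and -0.87 in control 1, 2 and 3 and 0.22 to 0.68 in knockouts, and the call was lost with the ventral-type secretory covariate (adjusted p = 0.214). In the extracellular matrix and fibroblast list 1 of 32 fell by either adjustment, Col6a3, a collagen VI chain named after its values were seen, from 426 to 29.3 CPM (adjusted p = 0.00282). Lum, Thy1 and Dcn had log2 fold changes of 1.06, 1.24 and 0.62, none past the threshold. In the TGF-beta list 1 of 21 fell, Ltbp2, and adjusted over the list alone 2 fell. Endothelial genes and nerve and Schwann cell genes had no member past the threshold by either adjustment among 17 and 10. None of these 4 lists passed as a set (adjusted p of 0.205 to 0.938 by camera). In skeletal muscle genes 2 of 10 fell, the myosin heavy chain genes Myh1 and Myh2 (5.90 to 0.15 and 9.10 to 0.37 CPM; adjusted p = 0.00981 and 0.0110), and 3 fell adjusted over the list alone. Of these 10 skeletal muscle genes 5 had positive log2 fold changes. The set was lower by camera (adjusted p = 0.0207), with an adjusted p = 0.753 with an estimated correlation. By camera it missed the threshold without control 2 (0.255) or knockout 3 (0.105). Adipocyte genes had no member past the threshold among 13 by either adjustment. Their list median stood at 4.49 in control 3 and at -2.49 to 0.58 in the other 5 libraries.

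**Figure D3:**
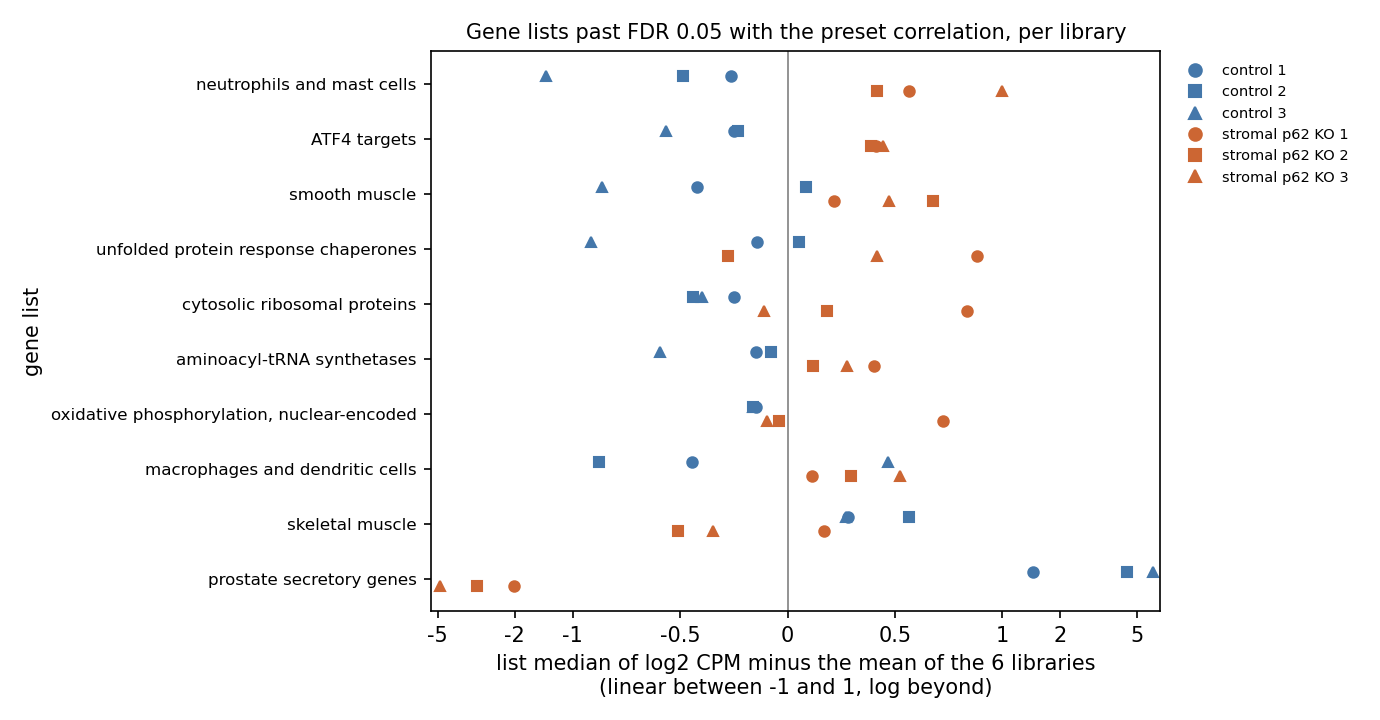
Median log2 level per library, relative to the mean of the 6 libraries, for the 10 gene lists past FDR 0.05 by camera with the preset correlation, on an axis that is linear between -1 and 1 and logarithmic beyond. The groups did not overlap in any of these lists except unfolded protein response chaperones and macrophages and dendritic cells. The ATF4 list was at -0.57 to -0.23 in controls and 0.39 to 0.45 in knockouts, and oxidative phosphorylation was at 0.72 in knockout 1 and at -0.09 and -0.04 in the other 2 knockouts.

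In the luminal and androgen-responsive list 3 of 23 fell and none rose, and adjusted over the list alone 6 fell. Fkbp5, an androgen- and glucocorticoid-induced chaperone, fell from 601 ± 389 to 45.8 ± 8.88 CPM, Slc45a3 from 392 ± 101 to 94.3 ± 35.4 CPM and Homer2 from 20.4 ± 3.37 to 1.21 ± 0.51 CPM (adjusted p = 0.00567, 0.0130 and 0.00122, edgeR). Fkbp5 was at 350, 404 and 1049 CPM in control 1, 2 and 3, and Slc45a3 at 333, 335 and 509 CPM. Homer2 was lowest of the controls in control 3, at 17.6 CPM. The keratin genes Krt8 and Krt18 did not pass, with log2 fold changes of 0.06 and 0.25. The list median was 0.06, opposite in sign to its test (adjusted p = 0.128 by camera and 0.0361 by fry). In urothelium 1 of 8 fell by either adjustment, Upk1a, a uroplakin, from 121 ± 39.2 to 8.29 ± 1.02 CPM (adjusted p = 8.71e-04). The urothelium list did not pass as a set (adjusted p = 0.813 by camera). None of the 9 seminal vesicle genes in the table was abundant enough to test, with at most 1.29 CPM in any library.

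In the macrophage and dendritic cell list 3 of 22 members rose and 19 did not pass, and adjusted over the list alone 4 rose. The 3 were the class II genes H2-Eb1, from 34.1 ± 12.8 to 107 ± 27.6 CPM, H2-Ab1, from 24.5 ± 8.36 to 86.1 ± 32.0 CPM, and H2-Aa, from 43.8 ± 16.9 to 121 ± 29.8 CPM (adjusted p = 0.0253, 0.0274 and 0.0433, edgeR). With a library left out their calls were kept in 2, 2 and 1 of the 6 fits. The macrophage genes Csf1r and Adgre1 did not pass, with log2 fold changes of -0.04 and 0.36. The set was higher by camera (adjusted p = 0.00214), with an adjusted p = 0.841 with an estimated correlation, and missed the threshold without control 2 (0.0732). Control 3 had a list median of 0.47, within the knockout range of 0.11 to 0.52. In neutrophils and mast cells 1 of 6 rose by either adjustment, the mast cell chymase gene Cma1, from 1.65 ± 0.37 to 5.31 ± 1.08 CPM (adjusted p = 0.0321), a call lost in all 6 fits with a library left out. That set was higher by camera (adjusted p = 0.00463) and fry (0.0361), with an adjusted p = 0.441 with an estimated correlation. Only 6 of its 16 genes were tested, and the 4 with the smallest p, Cma1, Cpa3, Tpsb2 and Mcpt4, are mast cell genes. The set therefore says little about neutrophils. Its list median was -0.26, -0.49 and -1.37 in control 1, 2 and 3. T and NK cell genes (16) and B and plasma cell genes (10) had no member past the threshold by either adjustment. In the interferon list 1 of 27 rose (Iigp1) and 1 fell (Ifit2, adjusted p = 0.0426, a call kept in 1 of the 6 fits with a library left out), and 4 rose and 3 fell adjusted over the list alone. In the inflammatory and NF-kappaB list 1 of 20 fell by either adjustment, Nfkb1 (adjusted p = 0.0400), whose call was lost in all 6 such fits. None of these last 4 lists passed as a set (adjusted p of 0.205 to 0.577 by camera).

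Lists of protein synthesis, folding and stress were highest in knockout 1. Of 43 cytosolic ribosomal protein genes 42 had positive log2 fold changes with a median of 0.62, and none passed by either adjustment. The set was higher by camera (adjusted p = 2.74e-07), with an adjusted p = 0.841 with an estimated correlation, and its median was 0.84 in knockout 1, 0.19 in knockout 2 and -0.11 in knockout 3. Of 20 unfolded protein response chaperone genes none passed by either adjustment, and the set was higher by camera (adjusted p = 0.00333), with an adjusted p = 0.841 with an estimated correlation. Its median ran from -0.92 in control 3 to 0.88 in knockout 1, and without knockout 1 the adjusted p was 0.0772. In immediate early and heat shock genes 1 of 21 rose (Hspa1b) and 1 fell (Btg2), and adjusted over the list alone 4 rose and 1 fell. That set missed the threshold (adjusted p = 0.0509 by camera), and its median was 0.98 in knockout 1. None of 30 cell cycle genes and none of 16 hypoxia genes passed by either adjustment, and neither set passed (adjusted p = 0.435 and 0.948 by camera).

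Of 32 lists tested, 10 passed by camera with the preset correlation, 8 higher and 2 lower. None passed with an estimated correlation, the stricter setting, where 3 had an unadjusted p under 0.05, and 4 passed by fry. The estimated correlation was 0.50 for aminoacyl-tRNA synthetases, 0.54 for macrophages and dendritic cells and 0.60 for oxidative phosphorylation. It was 0.68 for smooth muscle, 0.68 for ribosomal proteins and 0.78 for chaperones. These lie far above the preset 0.01, so the preset p-values of these lists overstate the evidence. The other lists that passed had 0.011 to 0.155. The sign of the median and of the camera test differed for glycolysis, serine and glycine metabolism, luminal epithelium, NRF2 targets, interferon response and urothelium, of which none passed by camera.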

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

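Leaving out control 3 with knockout 1, and the ventral-type secretory covariate, were chosen after the data were seen. The count of 698 changed genes was 1582 in DESeq2, 1389 in limma-voom with quality weights, 1190 at an FDR of 0.10, 1229 without control 3 and knockout 1, and 170 with the covariate. Leaving out 1 library gave 255 to 551 genes, with fewer samples in each fit. The other alternatives gave 614 to 703. The share of lower genes was 73.5% in DESeq2 and 76.5% with quality weights against 91.8%, and the cause was not tested.

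Atf4 stayed higher under each alternative. It passed the threshold with a log2 fold change of 1.36 under upper-quartile factors, 1.20 with library size alone, 1.32 in DESeq2, 1.37 in limma-voom, 1.04 with quality weights and 0.87 without control 3 and knockout 1. The adjusted p ranged from 7.41e-04 to 0.808, and log2 fold changes were 1.06 to 1.51 with 1 library left out. Sqstm1 was past the threshold under none, at 0.05 to 0.50 (adjusted p 0.282 to 0.983). The ATF4 list lost its call only in camera with an estimated correlation (adjusted p = 0.231), and with the covariate its adjusted p was 0.0335. Its estimated correlation was 0.011, near the preset 0.01, so a higher correlation does not account for that loss. The 10 lists became 0 with an estimated correlation, 4 by fry and 16 with the covariate, and 9 to 15 with 1 library left out.

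The other named genes gave 3169 values over 17 alternatives: 2815 stayed on the same side of the threshold, 192 lost the call, 161 gained it and 1 reversed. Of the 2815, 27 had the other sign with no call on either side. The other 31 lists gave 434 values, of which 373 stayed on the same side (20 with the other direction), 28 lost the call, 32 gained it and 1 reversed. With the covariate Tgm4 had a log2 fold change of -5.26, and adipocyte genes were higher (adjusted p = 5.28e-06). The covariate is near 0 in all knockouts, so it overlaps the genotype and its fit extrapolates. Without each library in turn, 3 of the 12 largest rises and 8 of the 12 largest falls kept their call in all 6 fits. With the covariate 0 of these rises and 10 of these falls kept it, but Sbp, Sbpl and Spink1 among the falls define the covariate, so the 2 counts cannot be set against each other. A lost call was not always a lost rise. Under all alternatives the log2 fold change was at least 2.40 for Egflam and 1.97 for Arntl, but it went down to 1.07 for Adm2. In simulated data 2-fold changes were mostly missed (5 of 100 found). Fewer genes were changed there than the 698 called here, which makes the adjusted threshold stricter, so recovery in the real data may be higher.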

Other observations

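The tests of gland shares, of secretoglobin genes, of the ATF4 list against those shares and of knockout 1 were chosen after the results were seen. The test of other splits was chosen before. That of the clock genes was written before its outcome was seen, but the rise of Arntl from which it starts came from these data. The report gives Arntl as a gene that rose, and other genes of the daily clock also differed between groups. Per2 fell from 25.1 ± 6.30 to 5.35 ± 1.12 CPM (SD, n = 3 each; log2 fold change -2.22 ± 0.28 SE; adjusted p = 0.00505, edgeR), and Tef fell by 1.65 ± 0.28 on the log2 scale (adjusted p = 0.0178). Npas2, a partner of the BMAL1 family of factors, had a log2 fold change of 1.35 (adjusted p = 0.0962). Against the phase of Arntl, Nfil3 was at 60.0 ± 28.1 CPM in controls and 21.4 ± 11.3 CPM in knockouts (unadjusted p = 0.0123, adjusted p = 0.122), and Cry1 had a log2 fold change of -0.35 (adjusted p = 0.507). Dbp and Per3 had -1.14 and -1.25 (adjusted p = 0.115 and 0.0737), while Nr1d1 had -0.37 and Per1 had 0.26. The 10 genes that oppose Arntl in the daily cycle had a median log2 fold change of -0.755, and the 4 others in phase with it had 0.09. A different hour of harvest predicted a fall of the opposing genes, which was met. It also predicted a clear rise of the genes in phase, which was not met. Hours of harvest are not given in the labels, and with this mixed outcome the test could not tell a different hour from genotype.

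Among other abundant genes, the chloride cotransporter gene Slc12a2 fell by 8.10 ± 0.65 on the log2 scale from 4952 CPM (adjusted p = 0.00101, edgeR), and Pigr, the receptor that carries IgA across epithelium, from 3389 to 112 CPM (adjusted p = 0.00488). The long noncoding RNA Neat1 fell from 4825 to 1414 CPM (adjusted p = 0.0218). The kinase gene Sgk1 rose from 181 to 547 CPM (adjusted p = 0.0191), and the amino acid transporter gene Slc7a8 from 45.2 to 124 CPM (adjusted p = 0.0109). The Fc receptor gene Fcgr4 rose from 0.26 to 2.14 CPM and the nucleic acid sensor gene Zbp1 from 0.65 to 3.13 CPM (adjusted p = 0.00712 and 0.0274). With a library left out the calls of Neat1 and Zbp1 were kept in 1 of the 6 fits each, and those of Sgk1 and Tef in 3. These genes were chosen after their values were seen.

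Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave 698 genes, and the highest of the others gave 0. With 10 splits the share cannot go under 0.1, so these splits are too few to exclude chance. Every other split also mixes control and knockout libraries, so the difference between groups adds to its spread and holds its count down.

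Of the 641 lower genes, 580 (90.5%) were also higher in control 3 than in the mean of control 1 and 2. Random sets matched on expression gave 44.8% to 52.3%. Control 3 is in both comparisons and is the control that differs most from the others, so this share is no independent test. A candidate explanation is that libraries held different shares of 2 kinds of gland, a ventral-type one abundant in control 3 and one abundant in the knockouts. Genes of the control 3 kind (51) stood in control 1 and 2 at medians of 0.435 and 0.399 of control 3, genes of the knockout kind (36) at 0.605 and 0.514 of the knockout, and the sums averaged 0.976, close to 1. Of 5 abundant secretory genes 2, Tgm4 and Pbsn, differed by over 10-fold among the controls. The controls share a genotype label, so the labelled genotype does not account for this spread. It rests on control 3 and restates the observation that prompted the test, so it does not tell what lowered genes in the knockouts. All 9 Scgb genes that fell, a family with uncertain reads, stood in control 1 and 2 over 1.5-fold above control 3 and the knockouts. A mixture of 2 kinds does not give this, which held for 18 of all 641 lower genes (2.8%). Whether ventral-type tissue was missing from the knockout samples through dissection or through genotype was not tested, and a direct effect of genotype on these genes stays open.

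The higher ATF4 targets were set against the same mixture. If gland shares alone set them, control 1 and 2 should lie between control 3 and the knockout at the share of control 3 type given by the marker genes, 0.379 (bootstrap interval over genes 0.285 to 0.480). Over the 37 list members that share was 0.663 (0.583 to 0.722), at 0.657 in control 1 and 0.668 in control 2, so targets in these controls were lower than the gland shares give. This argues against shares of these 2 kinds as the whole cause, although the intervals cover genes and not libraries. It cannot weigh gland or tissue make-up more widely, because the Scgb genes already depart from a mixture of 2 kinds. The control 3 end of the mixture also had an adipocyte list median of 4.49. Atf4 itself had a log2 fold change of 0.56 against 1.31 once the covariate was fitted. An effect of stromal p62 loss on ATF4 targets stays a hypothesis, and which cells carry the change was not tested.

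Ribosomal protein and oxidative phosphorylation lists were highest in knockout 1, where genes with short transcripts were in excess over knockout 2 and 3 (Spearman rho across genes -0.417 with transcript length, and genes are not independent replicates). The ribosomal list's median excess in knockout 1 was 0.802, inside the 0.571 to 0.983 of sets matched on length and expression, yet the list kept an adjusted p of 1.99e-04 by camera with the preset correlation without knockout 1, so that library alone does not account for this call, which had an adjusted p = 0.841 with an estimated correlation and 0.315 in fry. The length measure was changed to the principal transcript after exon union lengths, which overstate these transcripts, had put the list above its matched range of 0.353 to 0.737. The oxidative phosphorylation median was 0.804, just above the 0.456 to 0.786 of its matched sets, and its adjusted p without knockout 1 was 0.149, in line with a call that rests on that library. RNA quality, library preparation and genotype stay open for what remains.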
